A study of Homo sapiens with 7 samples.

How the data were processed

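RNA from the estrogen-receptor-positive breast cancer line MCF-7 and from MCF-7 cells that over-express the kinase Akt3 was hybridised to 7 two-colour Agilent arrays. Cells of each line had been given a control treatment, estrogen or the antiestrogen tamoxifen, which makes 6 RNA conditions, written here as MC, ME and MT for MCF-7 and AC, AE and AT for the Akt3 cells. The arrays were ME/MC, MT/MC, AC/MC, AE/ME, AT/MT, AE/AC and AT/AC, with the Cy5 RNA named first, and the direction of every ratio was taken from the dyes in the labels. Per the labels' protocols, 250 ng of total RNA was labelled per channel with added spike-in controls, and hybridisation lasted 17 h at 65 °C. The labels speak of a dye swap and of 3 independent treatments. All 7 arrays had the treated or the Akt3 RNA in Cy5, arrays of the opposite orientation were not analysed here, and how the 3 treatments entered the arrays is not given in the sources used here.

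The deposited scanner files held the mean intensity of each spot and the median intensity of its local background in both channels. Per the file headers, they were made with Agilent Feature Extraction 9.5.3.1, whereas the submitters' processing notes name version 9.1. The same deposited files held a log10 ratio of Cy5 over Cy3 that Feature Extraction had background-subtracted and normalised between dyes, per the file headers, and flags per spot for saturation, outliers and signal above background. The deposited series table held the same log10 ratio to 3 decimals or fewer, with a median of 0 on every array and a largest difference of 0.005 from the scanner files, so its scale, direction and centring were known. The genome build behind the probe positions in the files is not given in the sources used here.

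Each array had 45015 spots, of which 43376 belonged to 41000 different probes that were not controls. Median spot intensities were between 247 and 274 in red and between 112 and 119 in green, over median local backgrounds of 63 to 66 and 49 to 52.5. Between 64.7% and 73.4% of probes were well above background per channel. At most 1 spot per channel was saturated. Slopes of observed on expected log ratios of the spike-in controls lay between 0.946 and 0.972. The number of arrays limits the precision of every value.

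Intensities were background-corrected with normexp (offset 50) and normalised by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as non-uniform outliers were left out, spots of one probe were averaged, and a probe was kept if it was well above background in every channel of at least 1 of the 6 conditions, which left 29018 probes. Names came from the accession in the file for 23680 probes and from a current or older symbol for 3925, through the RefSeq gene table of assembly GRCh38.p14. For 13395 probes the name in the file was kept. A gene with several kept probes was represented by the brightest, which gave 21370 genes. Probes of the same gene were compared for AKT3, ESR1, GREB1, MYC, TFF1 and TFF3 only.

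The 7 arrays join the 6 conditions in 2 closed loops. Log2 ratios were therefore fitted together in limma with 5 coefficients, which leaves 2 residual degrees of freedom, and the errors were moderated with an intensity trend (prior degrees of freedom 9.35). A gene was called when its Benjamini-Hochberg adjusted p was below 0.05 and its absolute log2 fold change was at least 0.5. The residual is the disagreement between direct and indirect routes around a loop, so p-values and SEs measure array-to-array error and not the spread between cultures. The 9 tested contrasts were Akt3 cells over MCF-7 under each treatment, estrogen and tamoxifen over control in each line, and the difference of each response between the lines, called the estrogen and the tamoxifen interaction. A dye bias of a gene stays in the first 7 contrasts and cancels in the 2 interactions.

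Gene lists were fixed before the data were examined, 19 in number, which gave 171 list-by-contrast tests. They covered estrogen-induced and estrogen-repressed genes, DNA replication, mitosis, FOXO targets, sterol and fatty acid synthesis, glycolysis and hypoxia, interferon-stimulated genes, the ATF4 and unfolded protein response, p53 targets, apoptosis regulators, luminal markers, basal and mesenchymal markers, receptors and PI3K-Akt pathway members, estrogen receptor coregulators, drug transport and metabolism, fibroblast markers, haematopoietic markers and ribosomal proteins. Shifts were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all 171 tests, beside camera with an estimated correlation and fry. Of these tests 71 passed at the preset correlation, 0 with an estimated correlation and 72 by fry, which kept 50 of the 71 and lost 21. The genes named per contrast were up to 8 with the highest and up to 8 with the lowest log2 fold change among called genes with a symbol whose direct and indirect routes agreed in sign at an absolute value of at least 0.5, a panel of 12 genes (AKT1, AKT2, AKT3, ESR1, PGR, TFF1, GREB1, PDZK1, CXCL12, MYC, CCND1 and CCNG2), and up to 4 members per list with the smallest adjusted p. Of these, 1 gene is not reported by name, although it was tested and is counted.

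Alternatives fixed beforehand were Agilent's log ratio, the series table, no background subtraction, normexp offset 10, median centring, Aquantile scaling, no filter or a filter on all 14 channels, the mean of a gene's probes, other fold minimums, no intensity trend, the slide as a random block, leaving out each array, and a separate-channel fit with a dye term. That last fit used Aquantile-scaled channels with an intraspot correlation of 0.77. As 3 conditions were measured in both dyes, it can estimate a dye bias, but only from intensities compared between arrays. The log ratios themselves hold no information on dye bias, because it cancels around each loop. The arrays lay on 4 slides. Fixed slide terms could not be fitted because they use up the residual degrees of freedom, so a common within-slide correlation was estimated by maximum likelihood over all genes. Leaving out spots marked as population outliers, asking every route to pass the fold minimum, and brightness-matched random lists (10000 per list) were added after the data were seen.

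The fit was tested on simulated data of 21370 genes, 200 of them changed by known amounts. For the MT-MC contrast, 100% of genes changed by 1 on the log2 scale were called, and 49.3% of those changed by 0.5. With a simulated dye bias of 0.128 (SD on the log2 scale, the value estimated by the separate-channel fit), 21 unchanged genes were called in MT-MC, 28 in ME-MC and 20 in AC-MC, against 0 in the estrogen and 1 in the tamoxifen interaction. Without the fold minimum 4267, 4263 and 5199 unchanged genes passed the adjusted p in these 3 contrasts, against 8, 10 and 9 without dye bias, and 2 and 8 in the interactions. Adjusted p-values and counts at unadjusted p in the 7 single contrasts are therefore open to dye bias of that size. The SD of 0.128 is the spread of the per-gene estimates and holds their error, so the true dye bias may be smaller. These simulated counts may thus be too high.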

Results

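The study compared MCF-7, a breast cancer line that grows in response to estrogen, with MCF-7 cells made to over-express AKT3, one of the 3 Akt kinases of the PI3K pathway. Both lines were examined after a control treatment, estrogen or tamoxifen, an antiestrogen that binds the estrogen receptor. Expression was measured on 7 two-colour arrays with 1 array per ratio, and 21370 genes were tested. Fold changes come from 1 limma fit of all 7 arrays, in which each contrast rests on its own array and on the indirect route around a loop. The fitted routes closed with an SD of 0.21 on the log2 scale over genes in the estrogen loop and 0.14 in the tamoxifen loop. No ratio was repeated, and nothing in the labels ties an array to a separate culture. P-values here therefore measure the error between arrays and may be technical only. In each of the 171 list-by-contrast combinations the number of called members was the same adjusted over the list alone as over all genes. Loess kept the median of all genes within 0.022 of 0 in every contrast, while median centring without loess moved it by up to 0.51, so values are relative to the loess curve of each array. List counts of 5 or fewer often changed by more than 1.5 times when 1 array was left out, and only the larger of these moves are given below. With median centring the count of a list moved by more than 1.5 times in 136 of the 171 combinations, with Agilent's log ratios and with the series table in 70 each, and in the fit with a dye term in 39. A list count moved in 23 combinations each without background subtraction and with normexp offset 10, and in 2 with the slide as a random block. Any change from 0 counts as a move. Most list counts below therefore depend on the choice of loess or median centring, and fewer on the other settings. Median centring leaves any intensity-dependent dye difference in place, and all arrays had the same dye orientation. With it, ribosomal protein genes had medians of 0.79 to 1.80 in the 7 single contrasts.

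AKT3 itself was the most raised gene in Akt3 cells over MCF-7 with the control treatment, at a log2 fold change of 4.85 (SE 0.11, limma, adjusted p = 5.28e-11), which is 28.8-fold. Its probe lies on chromosome 1 from 241782764 to 241782823, as the files give it. It was well above background in all 7 channels of Akt3 RNA and in 4 of the 7 channels of MCF-7 RNA, so the parental level is poorly measured. A pair of other AKT3 probes was above background in at most 2 of the 14 channels and read −0.04 and 0.03 on the AC/MC array. Which part of the transcript the introduced gene carries is not given in the sources used here. AKT1 and AKT2 were not called, at −0.02 and −0.21, but AKT1 turned positive, past the fold minimum, with median centring.

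Besides AKT3, the control-treated Akt3 cells had higher IGFBP5, a binding protein of insulin-like growth factors, at 3.11 (SE 0.05, limma, adjusted p = 8.62e-12). CPE, carboxypeptidase E, was higher by 3.01, SPRR3, a cornified envelope protein, by 2.61, CTSF, a lysosomal cathepsin, by 2.55, and AREG, a ligand of the EGF receptor, by 2.41. GAGE12F stood at 4.02, but its probe carries the name GAGE7 in the files and the GAGE genes are near-identical copies, so the member is uncertain. ARHGAP9, a regulator of Rho GTPases, was not well above background in any MCF-7 control channel and stood at 2.45 (adjusted p = 2.84e-07), a size that is poorly measured. Among the lowest were the transcription factor MYC at −2.75 (SE 0.04, limma, adjusted p = 6.45e-12), PMP22 at −2.28, FAXDC2 at −2.15, the estrogen-induced gene GREB1 at −2.13, RFLNA at −2.13, the amino acid transporter SLC6A14 at −2.12 and the stress protein NUPR1 at −2.04. The second probe of GREB1 read −0.95 on the AC/MC array, against −2.37 for the brightest. MYC rests on its brightest probe, since a pair of others named MYC read 0.14 and −0.02 on the AC/MC array and between −0.06 and 0.32 on all 7. The probe at 0.14 was well above background in all 14 channels. The probe at −0.02 was so in only 3, none of them control RNA of either line, so it cannot show a fall. ESR1, which encodes estrogen receptor alpha, was lower at −0.79, and its dimmer probe read −0.28 on that array. In all, 3133 genes differed, 1732 higher and 1401 lower in Akt3 cells, 464 of them by at least 1 on the log2 scale.

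Genes of DNA replication were higher in control-treated Akt3 cells, with 22 of 37 measured members higher, 0 lower and 15 not called (median 0.58, camera adjusted p = 1.26e-10). RRM2, a subunit of ribonucleotide reductase, stood at 1.60 and the thymidine kinase TK1 at 1.42. Of 36 mitosis genes 10 were higher and 0 lower, among them PTTG1 (securin) at 1.12 and CDK1 at 0.79. With median centring 33 of them were higher, and 6 in the fit with a dye term. Among genes of sterol and fatty acid synthesis 12 of 29 were higher and 0 lower, such as ACAT2 at 1.43 and the desaturase SCD at 1.01. For glycolysis and hypoxia 12 of 29 were higher and 4 lower, led by LDHA at 1.76, PGK1 at 1.08 and PKM at 1.11. Interferon-stimulated genes were higher in 13 of 26 cases and lower in 0, with IFI6 at 2.09 and ISG15 at 1.81. Targets of FOXO, the transcription factors that Akt inhibits, were lower in 13 of 24 cases and higher in 1. Their median was −0.62 with loess (camera adjusted p = 4.05e-05), but the median was 0.04 with median centring in place of loess. The insulin receptor substrate IRS2 stood at −1.82, PIK3IP1 at −1.44 and the cyclin CCNG2 at −1.25. Both estrogen lists leaned lower, with 14 of 40 estrogen-induced genes lower and 4 higher (median −0.24, but 0.34 with median centring), and 12 of 22 estrogen-repressed genes lower and 4 higher (−0.56, but 0.14). CA12, an estrogen-induced carbonic anhydrase, stood at −1.82 and the trefoil factor TFF3 at −1.94, with −0.82 for another of its probes on the AC/MC array. Basal and mesenchymal markers were lower in 5 of 21 cases and higher in 2 (median −0.21, but 0.06 with median centring), with CD44 at −1.15. Of the receptor and PI3K-Akt list 7 of 40 were lower and 4 higher (median −0.22, but 0.36 with median centring). Ribosomal protein genes had a lower median of −0.25, which turned to 0.80 with median centring, with 1 of 24 called, RPS9 (adjusted p = 1.44e-08). No list shift passed with an estimated correlation (adjusted p = 0.489 to 0.703 with an estimated correlation over the 11 lists called here), which with 2 residual degrees of freedom is estimated poorly, and fry called 9 of the 11. By limma fibroblast markers had 0 of 7 and haematopoietic markers 0 of 8 members called, against 2 and 4 at an unadjusted p under 0.05.

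With median centring in place of loess, 8753 genes were higher and 458 lower and the median of all genes was 0.37, against which the FOXO targets lay at −0.33, the estrogen-repressed genes at −0.23 and the estrogen-induced genes at −0.03.

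**Figure D1:**
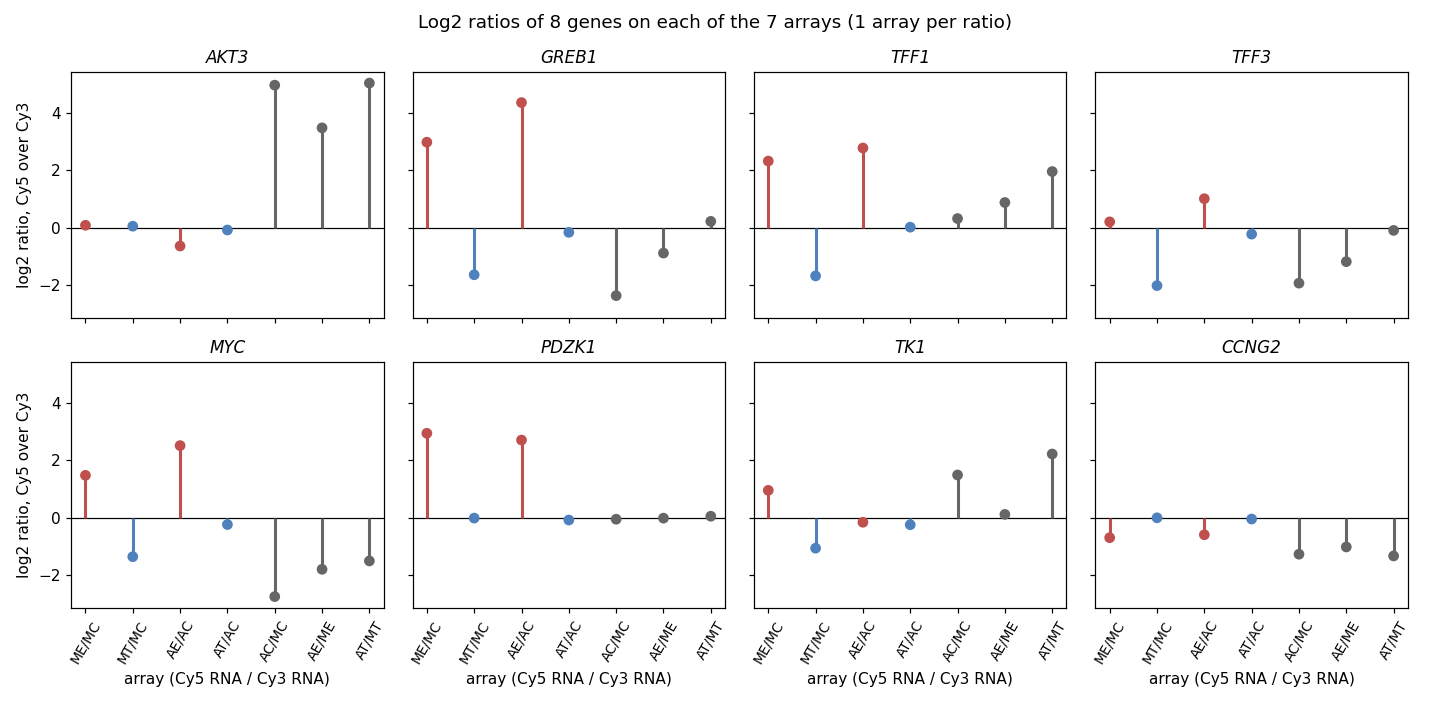
Log2 ratios (Cy5 over Cy3) of 8 genes on each of the 7 arrays, with 1 point per array. Estrogen over control is in red, tamoxifen over control in blue and Akt3 cells over MCF-7 in grey. TFF3 stood at −2.02 on MT/MC and at −0.23 on AT/AC, and AKT3 at 4.96 on AC/MC.

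With estrogen in both lines the Akt3 cells again had more AKT3, at 3.69 (SE 0.12, limma, adjusted p = 2.03e-09). AREG was higher by 3.19, CPE by 2.50, the glutathione transferase GSTM3 by 2.49, SPRR3 by 2.27, IGFBP5 by 2.12 and CTSF by 2.04, with GAGE12F at 3.78 and its member uncertain. SLC6A14 was lowest at −2.39 (SE 0.04, limma, adjusted p = 7.86e-11), followed by DEPTOR, an inhibitor of the mTOR kinase, at −2.03, MYC at −1.77, ACSS1 at −1.62, CABLES1 at −1.52, EVL at −1.52 and IRS2 at −1.51. TFF1 was higher at 0.84, and PGR, the progesterone receptor gene, was lower at −0.82, GREB1 at −0.84, CCND1 at −0.53, ESR1 at −0.53 and CCNG2 at −1.06. On the AE/ME array the second probe of ESR1 read −0.01, against −0.47 for the brightest. PGR read −0.60 there, and its 2 routes to the estrogen interaction gave −1.08 and −0.16, so its size is poorly measured. In all, 1746 genes differed, 1033 higher and 713 lower.

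Of 37 replication genes 1 was higher and 2 lower under estrogen (median 0.02), the licensing factor CDT1 at −1.02 being 1 of the lower, but 34 were higher and 0 lower with median centring (median 1.03, which is 0.53 above that of all genes). Of 36 mitosis genes 1 was higher and 3 lower (median −0.15, camera adjusted p = 0.0057, but a median of 0.93 with median centring). FOXO targets were lower in 9 of 24 cases and higher in 0 (median −0.35, but 0.35 with median centring), with TXNIP at −1.46. Estrogen-induced genes were lower in 16 of 40 cases and higher in 4 (−0.38, but 0.42), CCN5 standing at −1.12, and estrogen-repressed genes were lower in 10 of 22 and higher in 3 (−0.46, but 0.44), with CEACAM6 higher at 1.84. Glycolysis and hypoxia genes were higher in 10 of 29 cases and lower in 3. Interferon-stimulated genes were higher in 2 of 26 cases, ISG15 at 1.43 and IFI6 at 1.53, but in 10 without the AE/ME array, 9 without background subtraction and 11 with Agilent's log ratios. In the drug transport and metabolism list 7 of 19 were higher and 0 lower, with ABCG2, an efflux pump, at 1.04 and AKR1C1 at 1.30. Of the receptor and PI3K-Akt list 8 of 40 were lower and 2 higher (median −0.15, but 0.50 with median centring), and ribosomal protein genes had 1 higher and 1 lower (−0.15, but 1.43). The 9 lists called here had an adjusted p = 0.489 to 0.703 with an estimated correlation, and fry called 6 of the 9.

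Under median centring 10650 genes were higher and 296 lower in the estrogen-treated Akt3 cells, with a median of all genes of 0.51, and GREB1, ESR1, CCND1 and CCNG2 changed sign, to 0.16, 0.44, 0.72 and 0.04. Without the AE/ME array 2972 genes were called, and without background subtraction 2895.

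With tamoxifen in both lines the difference between them covered 3762 genes, of which 2208 were higher and 1554 lower in Akt3 cells. AKT3 stood at 4.93 (SE 0.12, limma, adjusted p = 1.32e-10), IGFBP5 at 3.51, CPE at 3.08, SPRR3 at 2.98, CTSF at 2.71 and the synaptic vesicle protein SV2B at 2.50, with GAGE12F at 4.30. ARHGAP9 stood at 2.64, again with MCF-7 channels not well above background. The lowest were PMP22 at −2.22 (SE 0.06, limma, adjusted p = 1.47e-10), FAXDC2 at −2.09, SLC6A14 at −2.07, PLAAT3 at −1.99, IRF2BP2 at −1.96, the septin SEPTIN10 at −1.94, BEX2 at −1.91 and the Wnt inhibitor DKK1 at −1.89. TFF1 was higher at 1.97 and MYC lower at −1.55, although with the mean of its probes MYC was not called, at −0.44.

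Under tamoxifen 32 of 37 replication genes were higher and 0 lower in Akt3 cells (median 0.94, camera adjusted p = 6.44e-14), including RRM2 at 2.11, CDC45 at 1.74 and the recombinase RAD51 at 1.59. Mitosis genes were higher in 22 of 36 cases and lower in 0, with PTTG1 at 1.27, CDK1 at 1.05 and survivin, BIRC5, at 0.93. FOXO targets were lower in 14 of 24 cases and higher in 1 (median −0.61, but 0.02 with median centring), with IRS2 at −1.80 and PIK3IP1 at −1.63. Estrogen-repressed genes were lower in 13 of 22 cases and higher in 1 (−0.63, but 0.14), YPEL3 standing at −1.41, whereas estrogen-induced genes went both ways, 7 higher and 9 lower of 40, a list that was not called (median −0.09, but 0.46 with median centring, camera adjusted p = 0.167). Sterol and fatty acid synthesis genes were higher in 12 of 29 cases and lower in 1, glycolysis and hypoxia genes in 13 and 4 of 29, and interferon-stimulated genes in 13 and 0 of 26, with LDHA at 2.17 and IFI6 at 2.14. Of the receptor and PI3K-Akt list 11 of 40 were lower and 4 higher (median −0.14, but 0.54 with median centring), and ribosomal protein genes were lower in 3 of 24 cases (−0.27, but 0.79). Over the 9 lists called here the adjusted p = 0.489 to 0.703 with an estimated correlation, and fry called 7 of the 9.

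With median centring 9321 genes were higher and 1579 lower in tamoxifen-treated Akt3 cells (median of all genes 0.42). Of the 1732 genes higher in Akt3 cells under control treatment 1554 were also higher under tamoxifen, against 179 expected of independent lists, and the 2 contrasts share error with a correlation of 0.30 through the loops.

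Estrogen raised GREB1 in MCF-7 by 3.02 on the log2 scale (SE 0.15, limma, adjusted p = 2.68e-08), the scaffold protein PDZK1 by 2.88, TFF1 by 2.28 and PGR by 1.36. LOXL4, a lysyl oxidase, rose by 2.97, the transcription factors MYBL1 and MYB by 2.53 and 2.15, RASGRP1 by 2.24 and RAB7B by 2.15. TGFB3, a TGF-beta ligand, fell to −2.44 (SE 0.06, limma, adjusted p = 1.29e-10), PMP22 to −2.39, CEACAM6 to −2.28, the cystatin CSTA to −2.26, the stress cytokine GDF15 to −2.08, RFLNA to −2.06, CYP1A1 to −2.05 and HILPDA to −1.91. MYC rose by 1.50, CXCL12 by 0.94 and CCND1 by 0.52, and ESR1 fell to −0.54 and CCNG2 to −0.74. On the ME/MC array the second probe of ESR1 read −0.27, against −0.48, and that of GREB1 also read nearer 0 than the brightest, at 2.97. PGR read 1.57 on that array, and its 2 routes to the estrogen interaction gave −1.08 and −0.16, so the size of its rise is poorly measured. In all, 2278 genes changed, 1253 up and 1025 down.

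Of the 40 estrogen-induced genes 32 rose and 0 fell in MCF-7 (median 0.97, camera adjusted p = 2.45e-18), and of the 22 estrogen-repressed genes 16 fell and 0 rose (median −0.83), but 7 fell and 3 rose with median centring (−0.34). Replication genes rose in 35 of 37 cases and fell in 0, with thymidylate synthase, TYMS, at 1.40 and RAD51 at 1.25. Mitosis genes rose in 35 of 36 cases and fell in 0, with NDC80 at 1.21 and CENPF at 1.11. Sterol and fatty acid synthesis genes rose in 11 of 29 cases and fell in 0, SCD by 1.36. Targets of p53 fell in 5 of 24 cases and rose in 0 (median −0.25, but 0.18 with median centring), and apoptosis regulators fell in 5 of 25 and rose in 1 (−0.18, but 0.28). The pro-apoptotic genes BMF, at −1.60, and BIK, at −1.53, were among those that fell, while the survival gene BIRC5 rose by 0.72. FOXO targets fell in 5 of 24 cases and rose in 1 (median −0.11, but 0.28 with median centring), and 2 of 24 ribosomal protein genes rose (median 0.28), but 5 without the ME/MC array and 23 with median centring (median 1.13). Luminal markers fell in 9 of 24 cases and rose in 4, a list that was not called (median −0.24, but 0.21 with median centring, camera adjusted p = 0.107), with ELF3 at −1.72 and AGR2 at 1.24. Estrogen receptor coregulators fell in 5 of 23 cases and rose in 2 (median −0.02, but 0.31 with median centring, camera adjusted p = 0.443), the pioneer factor FOXA1 standing at −0.68. The 9 lists called here had an adjusted p = 0.489 to 0.64 with an estimated correlation, and fry called 8 of the 9.

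Median centring gave 5271 genes up and 809 down in MCF-7 with estrogen, with a median of all genes of 0.26, and moved ESR1 to 0.00. AKT1 was called at −0.75, but stood at −0.25 and was not called in the fit with a dye term.

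In Akt3 cells estrogen raised GREB1 by 4.31 (SE 0.15, limma, adjusted p = 6.91e-09), TFF1 by 2.80, PDZK1 by 2.76, CA12 by 2.53, MYC by 2.48, LOXL4 by 2.39, the transcription factor EGR3 by 2.34 and AREG by 2.32. CXCL12 rose by 1.34. PGR was called at 0.70 but read 0.49 on the AE/AC array, no channel of Akt3 control RNA was well above background for it, and the fit with a dye term did not call it, at 0.52. The second probe of GREB1 read 2.13 on that array, against 4.35 for the brightest. CSTA fell to −2.00 (SE 0.05, limma, adjusted p = 4.04e-10), TGFB3 to −1.89, HOPX to −1.81, UPK1A to −1.68, PSCA to −1.61, BAMBI to −1.56, CREB3L4 to −1.39 and SERHL2 to −1.38. In all, 1638 genes changed, 949 up and 689 down. Of the 1253 genes that rose in MCF-7, 549 also rose in Akt3 cells, against 55.6 expected of independent lists, and of the 1025 that fell 434 also fell, against 33. The fits of both contrasts share error with a correlation of 0.36 and have the same dye orientation, so some overlap would arise without a shared response.

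Estrogen-induced genes rose in 29 of 40 cases and fell in 0 in Akt3 cells (median 0.99, camera adjusted p = 2.56e-18), with SUSD3 at 2.17, and estrogen-repressed genes fell in 16 of 22 and rose in 0 (median −0.67, but 0.04 with median centring), with ERBB2 (HER2) at −1.12. Replication genes rose in 2 of 37 cases and fell in 0 (median 0.24, camera adjusted p = 0.000839), TYMS by 0.72, but in 35 cases with median centring (median 1.03, which is 0.63 above that of all genes). Mitosis genes rose in 10 of 36 and fell in 0, with CENPA at 0.68, but in 36 with median centring and in 3 in the fit with a dye term. Ribosomal protein genes rose in 9 of 24 cases and fell in 0 (median 0.44), with RPL8 at 0.69 and RPL5 at 0.66. They rose in 5 without the AE/AC array and in 3 in the fit with a dye term. They rose in up to 12 without another array and in 24 with median centring (median 1.80). Apoptosis regulators fell in 5 of 25 cases and rose in 1 (median −0.10, but 0.65 with median centring), BMF standing at −1.29. Luminal markers fell in 6 of 24 cases and rose in 2 (median −0.28, but 0.62 with median centring, camera adjusted p = 0.00085), with ELF3 at −1.18 and SPDEF at −1.11, and interferon-stimulated genes fell in 3 of 26 and rose in 2 (−0.11, but 0.15), with 7 falling without the AE/AC array. The 8 lists called here had an adjusted p = 0.489 to 0.62 with an estimated correlation, and fry called 6 of the 8. On the ME/MC and AE/AC arrays, which share no RNA, log ratios correlated at r = 0.749 over 21370 genes, which are not independent replicates. Their covariance was 0.0717, against a variance of 0.0163 for the estimated dye terms, which holds their estimation error.

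Median centring gave 9022 genes up and 1057 down with estrogen in Akt3 cells, with a median of all genes of 0.40. AKT3 was called at −0.86 but turned to 0.52 in the fit with a dye term, and AKT1, at −0.84, was not called there, at −0.34.

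**Figure D2:**
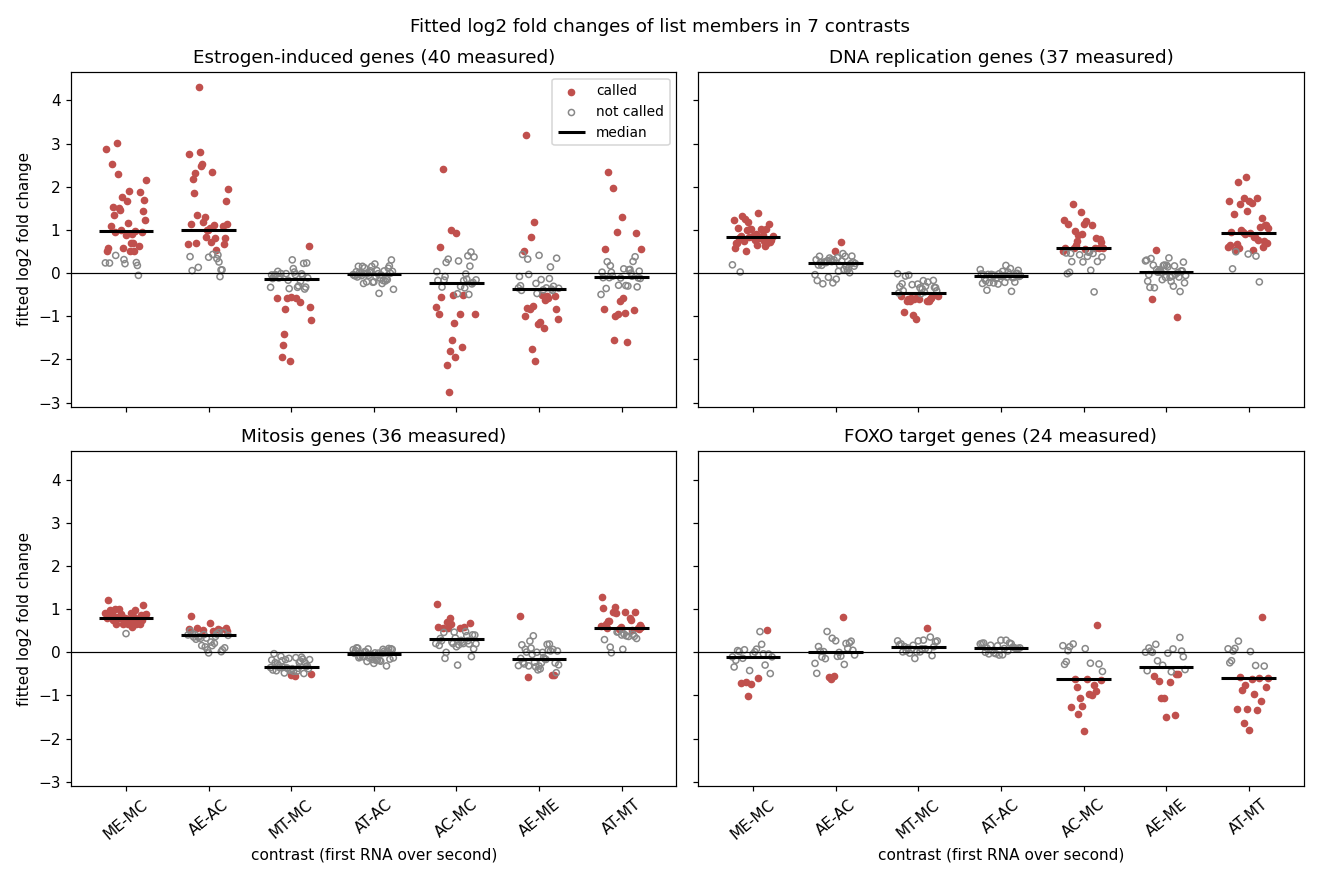
Fitted log2 fold changes (vertical axis) of the measured members of 4 gene lists in 7 contrasts, with filled points for called genes, open points for others and bars for medians. The medians of DNA replication genes were 0.84 in ME-MC, 0.24 in AE-AC, −0.46 in MT-MC and −0.07 in AT-AC, the last turning to 0.28 with median centring.

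The estrogen interaction, the response in Akt3 cells minus that in MCF-7, singled out genes that responded to a different extent in the 2 lines. RFLNA (2.07, SE 0.09, limma, adjusted p = 1.37e-07), PMP22 (1.60) and GDF15 (1.59), all lowered by estrogen in MCF-7, had the most positive differences, together with RASD1 at 1.45, GREB1 at 1.29, TM4SF1 at 1.28, PSG6 at 1.29 and PSG8 at 1.20. MYC, at 0.98, and TFF1, at 0.52, rose further in Akt3 cells. RFLNA, PMP22, GREB1 and MYC already stood lower in control-treated Akt3 cells than in MCF-7. Under estrogen GREB1, MYC and PMP22 were still lower there. Whether starting levels give these differences was not tested. The second probe of GREB1 gave differences of only 0.13 and 0.41 by the 2 routes, against 1.38 and 1.48 for the brightest. The other MYC probes lay between −0.14 and 0.07, and 1 of them was well above background in only 3 of 14 channels. The most negative differences were those of TK1 at −1.24 (SE 0.07, limma, adjusted p = 4.3e-07), the metallothioneins MT2A at −1.23, MT1G at −1.15 and MT1L at −1.14, the sialyltransferase ST6GAL1 at −1.23, the imprinted RNA H19 at −1.18 and the kinetochore gene ZWINT at −1.13. AKT3 was called at −1.16, but the routes gave −0.72 and −1.49 and its MCF-7 level lay near background, so that size is poorly measured. Metallothioneins and pregnancy-specific glycoproteins are families of near-identical genes, so their members are uncertain. Of 9 measured metallothioneins 8 had a called negative difference (median −1.10), but 0 with median centring (median −0.72). Of 9 pregnancy-specific glycoproteins 5 had a called positive one, but 2 with median centring. With loess, metallothioneins also started higher in Akt3 cells with control (median 1.02) and stood near MCF-7 under estrogen (−0.08). Pregnancy-specific glycoproteins started lower in Akt3 cells with control, with 6 of 9 called lower (median −0.70). Under estrogen 0 of 9 were called lower (median −0.15), but 6 with median centring.

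In all, 688 genes had a called difference, 316 positive and 372 negative. Replication genes had a negative difference in 27 of 37 cases and a positive one in 0 (median −0.61, camera adjusted p = 1.02e-26), with RRM2 at −1.06 and RAD51 at −0.97, and mitosis genes in 12 and 0 of 36, with CDK1 at −0.84. With median centring 2 replication genes (median −0.25) and 0 mitosis genes (median −0.15) had a called negative difference. With loess, replication genes started higher in Akt3 cells (median 0.58 with control) and stood level with MCF-7 under estrogen (0.02). A weaker response was not told apart from a higher start. Sterol and fatty acid synthesis genes were negative in 7 of 29 cases and positive in 0 (median −0.24, but 0.07 with median centring), with SCD at −1.06, and interferon-stimulated genes in 2 and 0 of 26, with 7 negative without the ME/MC or the AE/AC array and 0 without the AC/MC or the AE/ME array or without background subtraction. The ATF4 and unfolded protein response list was positive in 7 of 28 cases and negative in 1, with DDIT3 (CHOP) at 1.10, ATF3 at 1.07 and ASNS at 0.80. FOXO targets were positive in 4 of 24 cases and p53 targets in 3 of 24, both with 0 negative, TRIB1 standing at 0.75. Ribosomal protein genes had a median of 0.16 with 0 of 24 called by limma and 11 above 0 at an unadjusted p under 0.05. With median centring positive differences were called in 5 genes of the ATF4 list, 0 FOXO targets, 1 p53 target and 2 ribosomal protein genes (median 0.67), and no interferon-stimulated gene was called (median −0.06). Over the 8 lists called here the adjusted p = 0.489 to 0.62 with an estimated correlation, and fry called 5 of the 8.

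Without the ME/MC or the AE/AC array 1110 genes were called, and median centring gave 189 positive and 67 negative calls (median of all genes 0.10). The call of MYC was lost with the mean of its probes, at 0.29.

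Tamoxifen lowered the trefoil factors TFF3, to −2.04 (SE 0.04, limma, adjusted p = 2.76e-10), and TFF1, to −1.66, in MCF-7, together with GREB1, to −1.94, and MYC, to −1.40. The p53-related TP63 fell to −1.14, MYB to −1.10, the retinoic acid hydroxylase CYP26B1 to −1.07 and CCND1 to −0.67. The RAS-related gene RASD1 rose by 1.23 (SE 0.04, limma, adjusted p = 4.26e-08), the noncoding RNA MALAT1 by 0.95, BMERB1 by 0.81, the heat shock gene HSPB1 by 0.78, ATF3 by 0.78, PAWR by 0.75, the keratin KRT19 by 0.71 and ADAD2 by 0.69. In all, 146 genes changed, 45 up and 101 down. ESR1 was not called, at −0.36. On the MT/MC array the second probe of GREB1 read −0.47, against −1.65 for the brightest, and another of TFF3 −0.65, against −2.02.

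Tamoxifen lowered 17 of 37 replication genes and raised 0 (median −0.46, camera adjusted p = 1.53e-26), with TK1 at −1.06, CDC45 at −0.98 and MCM7 at −0.91, but with median centring 0 fell (median −0.16). Of 36 mitosis genes 3 fell and 0 rose (median −0.34, but 0.03 with median centring), BIRC5 and FOXM1 among them at −0.56 and −0.53, and 5 fell when the MT/MC array was left out. Estrogen-induced genes fell in 12 of 40 cases and rose in 1 (median −0.15, but 0.00 with median centring), CA12 standing at −0.84, and estrogen-repressed genes rose in 2 of 22 and fell in 0, BCAS1 by 0.56. Among FOXO targets 1 of 24 rose, TXNIP by 0.56, and ribosomal protein genes had a median of 0.11 with 0 of 24 called by limma and 8 above 0 at an unadjusted p under 0.05. That median was −0.06 with Agilent's log ratios, −0.05 with the series table and 0.86 with median centring, where 17 of them rose. The 6 lists called here had an adjusted p = 0.489 to 0.683 with an estimated correlation, and fry called 3 of the 6.

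Median centring gave 498 genes up and 10 down with tamoxifen in MCF-7 (median of all genes 0.15). Without the MT/MC array 244 genes were called, and in the fit with a dye term HSPB1 stood at 0.02 and KRT19 at −0.21, neither called. In that fit 68 of the 146 genes were called and 145 kept their sign.

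In Akt3 cells tamoxifen changed 48 genes, 47 of them up, by at most 0.80 on the log2 scale. KRT19 rose by 0.80 (SE 0.10, limma, adjusted p = 0.00147), HSPB1 by 0.71, the melanosomal glycoprotein GPNMB by 0.68, SLITRK2 by 0.65, RHO by 0.60, the ribosomal protein genes RPS27 and RPS2 by 0.59 and 0.56, and the elongation factor EEF1D by 0.54, where RPS genes have many copies and are uncertain. TFF1 at −0.01, GREB1 at 0.12, PDZK1 at −0.06, MYC at −0.20 and ESR1 at −0.05 were not called. Estrogen-induced genes had 0 of 40 called by limma (median −0.03, but 0.23 with median centring, 13 below 0 at an unadjusted p under 0.05), replication genes 0 of 37 (median −0.07, but 0.28, 14 below 0 at such a p) and mitosis genes 0 of 36 (median −0.03, but 0.31, 11 below 0).

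Of 24 luminal markers 1, KRT19, was called (median −0.13, but 0.36 with median centring). By limma 0 of 24 FOXO targets (median 0.10, 11 above 0 at an unadjusted p under 0.05) and 0 of 24 ribosomal protein genes (median 0.19, 15 above 0) were called, but 22 ribosomal protein genes rose with median centring (median 0.93). These 3 lists and the estrogen-induced, replication and mitosis genes shifted by camera at the preset correlation, but fry called only 1 of the 6, and they had an adjusted p = 0.489 to 0.61 with an estimated correlation. On the MT/MC and AT/AC arrays, which share no RNA, log ratios correlated at r = 0.415 over genes, with a covariance of 0.00754. The estimated dye terms had a variance of 0.0163, which holds their estimation error, so the dye bias itself may be smaller. Covariances of an estrogen with a tamoxifen response in the other line were 0.00415 (ME/MC and AT/AC) and −0.00206 (MT/MC and AE/AC). How much of the correlation comes from dye bias was not determined.

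In the fit with a dye term 4 of the 48 genes were called, but 45 kept their sign and their median was 0.415, while KRT19 and HSPB1 turned to −0.13 and −0.05. Without the AT/AC array 1 gene was called, and the split was 808 up and 179 down with median centring (median of all genes 0.24) and 225 up and 32 down with Agilent's log ratios.

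The tamoxifen interaction, the response in Akt3 cells minus that in MCF-7, was led by genes that tamoxifen lowered in MCF-7. GREB1 stood at 2.06 (SE 0.17, limma, adjusted p = 6.24e-05), TFF3 at 1.83 (SE 0.05, adjusted p = 3.76e-09), TFF1 at 1.65, MYC at 1.20, CYP26B1 at 1.10, CDCA7 at 0.86 and CDC45 at 0.85. By the 2 routes the second probe of GREB1 gave 0.45 and 1.01 and another of TFF3 0.49 and 1.01, while both TFF1 probes gave 1.64 or more. Negative differences were those of RASD1 at −0.90, ADAD2 at −0.85, PAWR at −0.84, MALAT1 at −0.73, KCNF1 at −0.69, the glucose transporter SLC2A1 at −0.69, IER3 at −0.65 and ID1 at −0.64. In all, 171 genes had a called difference, 128 positive and 43 negative. Of the 101 genes lowered by tamoxifen in MCF-7, 37 had a called positive difference and 0 a negative one, and their median was −0.59 in MCF-7 and −0.16 in Akt3 cells.

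Estrogen-induced genes had a positive difference in 10 of 40 cases and a negative one in 0 (median 0.16, camera adjusted p = 3.78e-06), CA12 standing at 0.83, and replication genes in 8 and 0 of 37 (median 0.36), with TK1 at 0.81 and RAD51 at 0.61. With median centring 4 estrogen-induced and 0 replication genes had a called positive difference. Mitosis genes had a median of 0.25 with 0 of 36 called by limma and 32 above 0 at an unadjusted p under 0.05. Estrogen-repressed genes had a negative difference in 1 of 22 cases, BCAS1 at −0.52, and apoptosis regulators a median of −0.06 with 0 of 25 called by limma and 7 below 0 at an unadjusted p under 0.05. The 5 lists called here had an adjusted p = 0.489 to 0.497 with an estimated correlation, and fry called all 5.

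Without the AT/MT array 56 genes were called, among them 4 of the replication genes, against 16 replication genes without the MT/MC or the AT/AC array. Median centring gave 77 positive and 13 negative calls (median of all genes 0.02), and the mean of its probes ended the call of MYC, at 0.45.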

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

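Of the tests weighed below, the spike-in slope, the genes that start lower in Akt3 cells, the 3 tests of the replication genes, and the medians on the MT/MC and AE/AC arrays were chosen only after the result was seen. The genes and lists of the next paragraph were flagged because the response to a treatment differed between the 2 lines in a test of the difference itself, limma for genes and camera for lists. Of the 3 patterns weighed after them, the first is such a difference. The differences rest on 1 array per ratio.

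The response to estrogen differed in 688 genes and the response to tamoxifen in 171. Positive differences in the estrogen response (Akt3 cells minus MCF-7) were those of RFLNA at 2.07, PMP22 at 1.60, GDF15 at 1.59, RASD1 at 1.45, GREB1 at 1.29, PSG6 at 1.29, TM4SF1 at 1.28, PSG8 at 1.20, MYC at 0.98 and TFF1 at 0.52. Negative ones were those of TK1 at −1.24, MT2A at −1.23, ST6GAL1 at −1.23, H19 at −1.18, AKT3 at −1.16 (−0.72 and −1.49 by the 2 routes, with MCF-7 levels near background), MT1G at −1.15, MT1L at −1.14 and ZWINT at −1.13. With median centring no metallothionein had a called difference in the estrogen response. MYC rests on 1 of its probes, and the others did not move with it. Of these others, 1 was well above background in only 3 of 14 channels. The second probe of GREB1 gave only 0.13 and 0.41 in the estrogen response by the 2 routes. Starting levels were not weighed for the estrogen response, although MYC, GREB1, RFLNA and PMP22 were lower in control-treated Akt3 cells than in MCF-7. So were 6 of 9 measured pregnancy-specific glycoproteins. In the tamoxifen response GREB1 stood at 2.06, TFF3 at 1.83, TFF1 at 1.65, MYC at 1.20, CYP26B1 at 1.10, CDCA7 at 0.86 and CDC45 at 0.85, against RASD1 at −0.90, ADAD2 at −0.85, PAWR at −0.84, MALAT1 at −0.73, KCNF1 at −0.69, SLC2A1 at −0.69, IER3 at −0.65 and ID1 at −0.64. Median differences of the lists in the estrogen response were −0.61 for DNA replication, −0.45 for mitosis, 0.21 for FOXO targets, −0.24 for sterol and fatty acid synthesis, −0.24 for interferon-stimulated genes, 0.29 for the ATF4 and unfolded protein response, 0.22 for p53 targets and 0.16 for ribosomal proteins. In the tamoxifen response they were 0.16 for estrogen-induced genes, −0.15 for estrogen-repressed genes, 0.36 for DNA replication, 0.25 for mitosis and −0.06 for apoptosis regulators. With median centring these 8 stood at −0.25, −0.15, 0.40, 0.07, −0.06, 0.53, 0.45 and 0.67 in that order, and these 5 at 0.11, −0.10, 0.41, 0.30 and −0.01. None of these lists passed with an estimated correlation, the lowest adjusted p = 0.489 with an estimated correlation.

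Genes lowered by tamoxifen in MCF-7 fell less in Akt3 cells. Compressed ratios on the AT/AC array do not account for it, since its spike-in slope was 0.971, against 0.949 on MT/MC, and chance errors of the MT/MC array do not either, because the 89 genes at −0.5 or lower on that array had a median of 0.52 (quartiles 0.396 and 0.667) for AT/MT minus AC/MC, 2 arrays not used to select them. For the 74 of 101 genes with AC-MC at −0.2 or higher, the values argue against a starting level too low to fall further. As a set they had a median difference of 0.43 (quartiles 0.356 and 0.546). That difference holds the MT-MC value by which the genes were chosen, which favours a high one. For the other 27, GREB1, TFF3 and MYC among them, too low a starting level cannot be told apart. Their AC-MC minus MT-MC had a median of −0.17 (quartiles −0.486 and 0.123). An effect of Akt3, other differences between the 2 lines and an unusual tamoxifen culture stay open. The sample titles name no vector control and no second Akt3 line.

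Replication genes were higher in Akt3 cells than in MCF-7 with control treatment and with tamoxifen. Whether dye bias accounts for the first cannot be decided. The median was 0.59 in the fit with a dye term and 0.58 without it. That term rests on intensities compared between arrays, because the log ratios hold no information on dye bias. Dye bias as the whole cause would need an opposing difference between the lines under estrogen. The fitted AE-ME median, of the same dye orientation, was 0.02. With median centring that median was 1.03, against 1.33 in AC-MC. An atypical MCF-7 control RNA cannot give the second, because the AT/MT array holds no such RNA and had a median of 0.94 (quartiles 0.612 and 1.401). For the control treatment, where the AC/MC array had a median of 0.56, this could not be told apart from an effect of Akt3, since the labels name no second MCF-7 control RNA. Under both treatments an effect of Akt3 cannot be told apart from other differences between the lines, since the sample titles name no vector control.

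Genes called between tamoxifen and control in Akt3 cells were nearly all higher. The medians of these 48 genes on other arrays of the same dye orientation, the lowest being −0.42 on AC/MC, do not decide on dye bias, because AC/MC and AT/MT enter the fitted contrast by which the genes were chosen. The 48 genes had a median of −0.08 on MT/MC (quartiles −0.195 and 0.194), against 0.56 on AT/AC, although the loop fit favours genes high on MT/MC. For most, dye bias as the whole cause would thus need an opposing fall with tamoxifen in MCF-7. Their median of 0.415 in the fit with a dye term does not decide this, since the log ratios hold no information on dye bias. Dye bias in part remains open, and for KRT19 and HSPB1 as a whole, which stood at −0.13 and −0.05 in the fit with a dye term. Low readings of the Akt3 control RNA cannot be told apart from an effect of tamoxifen, with a median on AE/AC of 0.22 (quartiles 0.135 and 0.385).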

How the results depend on the processing

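The requirement that every route pass the fold minimum and the removal of population outlier spots were chosen only after the result was seen. Values follow the order AC-MC, AE-ME, AT-MT, ME-MC, MT-MC, AE-AC, AT-AC, estrogen interaction and tamoxifen interaction, where the main counts were 3133, 1746, 3762, 2278, 146, 1638, 48, 688 and 171. By construction, no fold minimum raised them to 11860, 8482, 11822, 10223, 3998, 9450, 2147, 5625 and 2139, and a log2 minimum of 1 lowered them to 464, 190, 694, 316, 10, 133, 0, 54 and 8. Asking every route to pass gave 1910 in AC-MC, 413 in the estrogen interaction and 106 in the tamoxifen interaction. Agilent's log ratios gave 5688, 4720, 5921, 3751, 873, 3000, 257, 1279 and 746, and the values of the series table gave 5683, 4713, 5914, 3780, 868, 3002, 255 (224 up, 31 down), 1293 and 740. Median centring gave 9211, 10946, 10900, 6080, 508, 10079, 987, 256 and 90. Without background subtraction AE-ME had 2895, MT-MC 287 and the tamoxifen interaction 281, and with normexp offset 10 AT-AC had 141 and the interactions 1115 and 270. AT-AC had 4 in the fit with a dye term, where 45 of the 48 genes kept their sign (median 0.415), and 25 without an intensity trend. Other than for the fold minimum and the routes, the cause was not tested. With all 7 arrays, all other counts stayed within 1.5 times the main one, among them those of Aquantile scaling, both other filters, the mean of probes and the slide block (within-slide correlation −0.32).

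Leaving out 1 array gave 2877 to 3391, 1633 to 2972, 3468 to 3936, 2277 to 3086, 124 to 244, 1649 to 2292, 1 to 52, 675 to 1110 and 56 to 214, where the contrast of the array left out rests on the indirect route alone. No paired analysis was possible because the labels give no replicate numbers and each group has 1 array. Fixed slide terms were not run, since they leave no residual degrees of freedom. Fold changes of dim genes are limited by signals near background, at median intensities of 112 to 119 in green over backgrounds of 49 to 52.5.

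Alternative values were computed for the highest, the lowest and the panel genes, and not for genes named only as list members. Of these values 4186 kept the same call or stayed not called, 117 became weaker, 35 stronger and 15 reversed. Sign changes of genes called in neither setting were not counted. With median centring AKT1 turned to 0.61 in AC-MC, 0.71 in AE-ME and 0.64 in AT-MT. In AE-ME ESR1 turned to 0.44, GREB1 to 0.16, CCND1 to 0.72 and CCNG2 to 0.038, in ME-MC ESR1 to 0.002 and in AE-AC CCNG2 to 0.28. In the fit with a dye term KRT19 turned to −0.21 in MT-MC and −0.13 in AT-AC, HSPB1 to −0.045 in AT-AC and AKT3 to 0.52 in AE-AC. AKT3 in MT-MC turned to 0.60 with Agilent's log ratios and 0.61 with the series table. The cause was not tested. List tests were repeated only with an estimated correlation, with fry, in the fit with a dye term and without each array. Of these 590 stayed called, 120 lost the call and 0 reversed, 71 of the losses with an estimated correlation. Direction was not compared for the estimated correlation and for fry, so no reversal could be counted there. The list tests were not run with other scalings, under which medians of lists do change sign.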

Other observations

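None of the values in this part comes from a test chosen only after the result was seen. ABCG2, an efflux pump, was higher in Akt3 cells under all 3 treatments, by 0.90 with control (SE 0.04, limma, adjusted p = 3.85e-09), 1.04 with estrogen and 1.02 with tamoxifen. Estrogen lowered ABCG2 in both lines, to −0.999 in MCF-7 and −0.87 in Akt3 cells. AKR1C1, a hydroxysteroid dehydrogenase, was higher by 1.34 in Akt3 cells with the control treatment (SE 0.11, adjusted p = 5.3e-07). CD44, a surface receptor for hyaluronan, rose with estrogen in Akt3 cells by 1.06 (SE 0.04, limma, adjusted p = 6.91e-09). It was not called in MCF-7, at 0.32, and the difference between the lines was called at 0.74 (limma, adjusted p = 7.37e-07). With control treatment CD44 already stood lower in Akt3 cells than in MCF-7. Whether that lower start gives the difference was not tested.

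The files give a calendar date as the gene name of 40 probes, of which 33 were named by accession.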
